A study of Mus musculus with 34 samples.

How the data were processed

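RNA was measured by bulk RNA sequencing in 34 samples of mouse ependymal cells, the multiciliated cells that line the brain ventricles. Per the labels, lateral ventricular walls were dissected from embryos at embryonic day 18.5, the cells were grown to confluency, and differentiation was induced by 4 days without serum. Total RNA was purified on RNeasy columns and made into libraries with the TruSeq RNA-seq protocol. The labels give C57BL/6 as the strain, while every sample title also carries the term OF1, which the labels leave unexplained. There were 6 groups, a knockout group and a group of wild-type siblings in each of 3 lines (Rfx1, Rfx2 and Rfx3), with 4, 6 and 6 knockout samples and 4, 8 and 6 wild-type samples. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate embryos or separate cultures, so each p-value measures only the spread between samples. No label gives a sequencing batch, a date or the sex of an embryo.

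The authors deposited raw read counts per Ensembl gene, with 1 column per sample and no normalization. Their processing notes name CASAVA 1.8.2, STAR 2.4 and featureCounts 1.4.6 with the GRCm38 genome. Settings, strandedness and the annotation release are not given in the sources used here. The table held whole numbers for 21647 genes, of which 21583 matched the GENCODE M21 annotation by Ensembl identifier and 20985 were protein-coding there. Gene symbols and positions were taken from that annotation. The 64 identifiers without a match held between 0.0341% and 0.0417% of a library's counts. All 34 columns matched a sample. Total counts per library ran from 18.2 to 53.4 M. Among 85 pairs of replicates, the counts differed by more than counting error in every pair (chi-squared per degree of freedom from 4.11 to 212), so no library was a copy of another in its group. Pairs across groups were not compared.

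Each line was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Libraries were scaled by TMM, and knockouts were tested against wild types with the two-sided quasi-likelihood F test. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 over all genes kept. The standard error of a log2 fold change was derived from that test. Differences between lines were contrasts of the knockout effects in a fit of all 34 libraries, and the wild-type groups were compared by an F test in the same fit. Levels are given as CPM with TMM scaling, as mean ± SD over libraries. Genes called in the same direction in 2 lines were counted among the genes tested in both and compared with independence by Fisher's exact test, one-sided and for each direction. Called genes within 10 Mb of the targeted gene were compared with all other genes tested by Fisher's exact test, one-sided, without the targeted gene.

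Before the data were examined, 36 gene lists with 683 symbols were written, for parts of the cilium, regulators of multiciliation, neighbouring cell types, signalling, stress and general metabolism. Of these symbols, 19 had no match in the table. Lists with at least 5 tested members, 33 in all, were tested in each line by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The adjusted p covered all 97 such tests. Camera with an estimated correlation called 0 of the 97 tests, with a lowest adjusted p of 0.572, against 36 with the preset correlation and 33 by fry, which tests only whether a list's genes move on balance in a direction. An exact permutation test of each library's mean over a list, added after those results were seen, called 32. None of these list tests used the replicate number as a block, and the exact test permuted genotypes over all splits of a line. Counts within a list are given over all genes tested and also adjusted over the list alone.

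Comparisons, tests, alternatives, lists and the rule for naming genes were all set before the data were examined, apart from the additions named as such. That rule took the targeted gene, the other RFX genes and Foxj1. It also took the 5 largest increases and 5 largest decreases among called genes with a mean log2 CPM of at least 1 and all knockouts on that side of the wild-type mean. Predicted genes were left out of that part. From the 5 lists with the smallest camera p, up to 3 members with the smallest p were added, and near the locus the 3 called genes with the smallest p. For differences between lines, the 3 called genes with the largest difference in each direction were named, again with a mean log2 CPM of at least 1 and without predicted genes, and for shared calls the 5 genes with the smallest larger p. Mcidas, Ccno, Pdgfra, Gfap, Gapdh and the other genes named outside this rule were chosen after their values were seen. Some results that this rule named are not reported.

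The replicate numbers were checked for pairing of knockout and wild-type samples through correlations of their deviations from the group means. In the Rfx2 line the 6 correlations lay between 0.16 and 0.61, all above the limit of 0.1 set beforehand, so values with the replicate number as a block are given where the block changed a call or moved a count by over 1.5 times. In the Rfx1 and Rfx3 lines, 3 of 4 and 1 of 6 passed that limit, and the numbers were not taken as pairs.

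Alternatives changed 1 choice at a time. They were scaling by RLE or by library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, at least 50 counts, the replicate number as a block, and robust dispersion. A surrogate variable from sva 3.50.0, libraries thinned to the smallest total, replicates 1 to 4 only, a fit of other groups, an adjusted p below 0.01, a log2 change of at least 1, a window of 5 Mb and each library left out in turn were also tried. A term for Y-linked counts (libraries with more than 10 CPM over 4 Y-linked genes) and the removal of each library's trend with transcript length were added after the data were seen. The median log2 fold change of all genes stayed within 0.03 of 0 under the 3 scalings.

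The fits were tested on simulated data with 200 changed genes, 50 for each size. With the sample numbers of the Rfx1, Rfx2 and Rfx3 lines, 43, 49 and 44 of 50 genes changed 2-fold were called, and 28, 41 and 28 of 50 changed 1.5-fold. Among unchanged genes, 4, 6 and 8 were called. For differences between lines, 41 (Rfx1 against Rfx2) and 44 (Rfx2 against Rfx3) of 50 were called at 2-fold. A shifted list was called and 0 of 31 other lists were. Simulated genes varied independently of each other, and the samples held no structure besides genotype. The simulation therefore does not show how often lists whose members move together are called wrongly. To ask how far reads can be placed, the share of each gene's 31-mers that also occur in transcripts of other genes was computed from the annotated transcripts. The mitochondrially encoded genes were absent from the table, and the list of blood genes had 0 tested members, so neither was tested.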

Results

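RNA was sequenced from cultured mouse ependymal cells from Rfx1, Rfx2 or Rfx3 knockouts, and from their wild-type siblings. These genes encode winged-helix transcription factors known to bind X-box motifs in the promoters of ciliary genes. The Rfx1 line had 4 knockout and 4 wild-type samples, the Rfx2 line 6 and 8, and the Rfx3 line 6 and 6. Total counts in Rfx1 knockouts ran from 18.2 to 22.5 M and in their wild types from 19.7 to 50.9 M. The Rfx2 line had 27.4 to 33.4 M in knockouts and 29.1 to 40.1 M in wild types, and the Rfx3 line 23.1 to 43.1 and 24.7 to 53.4 M. Between 15979 and 17245 genes were detected in a library. Y-linked genes were expressed in 1 of 4 Rfx1 knockouts and 4 of 4 of their wild types, in 3 of 6 and 4 of 8 in the Rfx2 line, and in 4 of 6 and 2 of 6 in the Rfx3 line. Each knockout was compared with its own wild-type siblings, to show which genes depend on the factor that was removed.

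In Rfx1 knockouts the level of Rfx1 mRNA (ENSMUSG00000031706, chromosome 8, 84066834 to 84096992) was 24.97 ± 4.95 CPM (SD, n = 4), against 65.9 ± 10.4 CPM (n = 4) in wild types. Knockout values ran from 19.5 to 29.9 and wild-type values from 52.0 to 76.9. The log2 difference was -1.40 (SE 0.16), with 4 of 4 knockouts below, and its adjusted p in edgeR was 0.0687, above the threshold over all genes tested. Rfx1 passed when adjusted over the RFX list alone, with DESeq2 (adjusted p = 1.63e-12), with no low-count filter (0.0438), without Rfx1_KO replicate 2 (0.0377) and in a fit of all groups (9.85e-08). In Rfx2 knockouts Rfx2 mRNA (ENSMUSG00000024206, chromosome 17, 56775897 to 56831013) fell to 49.0 ± 4.42 CPM (n = 6; 43.2 to 55.1) from 107 ± 16.0 (n = 8; 82.8 to 129), a log2 difference of -1.13 (SE 0.10, adjusted p = 1.34e-05). In Rfx3 knockouts Rfx3 mRNA (ENSMUSG00000040929, chromosome 19, 27761721 to 28011166) fell to 39.9 ± 9.22 CPM (n = 6; 24.9 to 51.7) from 176 ± 18.2 (n = 6; 158 to 208), a log2 difference of -2.14 (SE 0.15, adjusted p = 4.16e-05). In both lines 6 of 6 knockouts lay below every wild type.

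**Figure D1:**
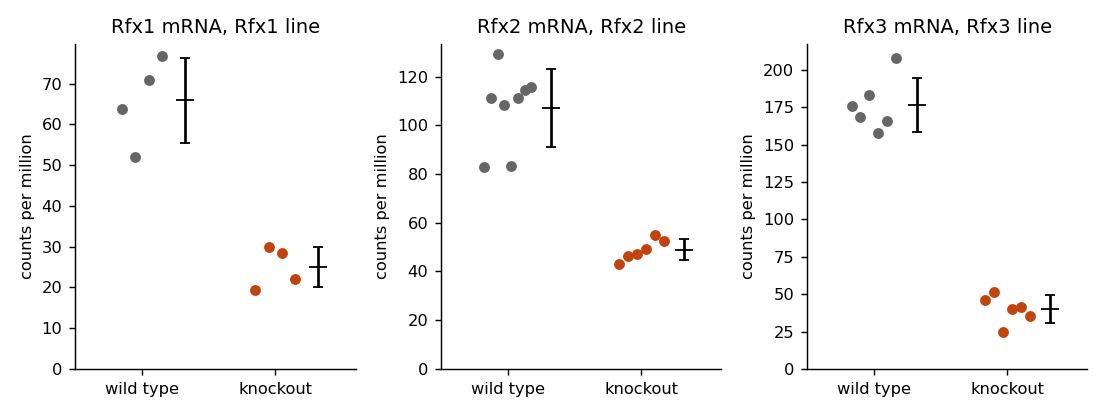
Counts per M of the targeted gene in each library (points) of the 3 lines, with the mean and SD of each group (bar). Knockout values lie below all wild-type values in each line, and none reaches 0.

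The other RFX genes and Foxj1, the master regulator of motile cilia, were measured in each line. In Rfx1 knockouts none of them passed. Rfx2 mRNA differed by 0.17 (log2), Rfx3 by 0.27 (179 ± 19.2 CPM against 149 ± 8.22, n = 4 and 4), Rfx4 by 0.09 and Foxj1 by -0.08, each with an adjusted p of 0.9998. Rfx5 (0.02), Rfx7 (0.03), Rfx8 (-0.04), Rfxap (-0.05) and Rfxank (-0.02) had the same adjusted p. Adjusted over the list alone, 1 RFX gene was higher and 1, Rfx1, lower. In Rfx2 knockouts Foxj1 fell to 745 ± 61.3 CPM (n = 6) from 1141 ± 209 (n = 8; log2 difference -0.62, SE 0.11, adjusted p = 0.000978). Rfx8, at 0.327 against 0.606 CPM, was called (-0.89, SE 0.32, adjusted p = 0.0434) but did not pass over the list alone. Rfx8 was not called with limma-voom (0.0519), no low-count filter (0.0519), the replicate block (0.103), a surrogate variable (0.0625), replicates 1 to 4 only (0.0873) and the length trend removed (0.0536), nor without Rfx2_KO replicates 1 (0.0926), 2 (0.0758), 3 (0.0726), 4 (0.0762) and 5 (0.0628), or Rfx2_WT replicates 1 (0.0566), 3 (0.0713), 5 (0.0509) and 8 (0.0793). Rfx1 (-0.11, adjusted p = 0.220), Rfx3 (-0.06, 0.652), Rfxank (0.11, 0.1003), Rfx4 (-0.04), Rfx5 (-0.07), Rfx7 (-0.02) and Rfxap (0.02) did not pass. Of these, Rfx1 passed without Rfx2_WT replicate 1 (0.0325) and Rfxank without Rfx2_KO replicate 6 (0.0448). In Rfx3 knockouts Rfx1 fell to 47.3 ± 7.41 CPM from 64.6 ± 6.79 (n = 6 and 6; -0.45, SE 0.11, adjusted p = 0.0111), and Rfx2 fell to 79.96 ± 18.2 from 118 ± 4.77 (-0.56, SE 0.12, adjusted p = 0.00861). Both calls ended when only replicates 1 to 4 were used (adjusted p = 0.142 and 0.134). Foxj1 was 1083 ± 383 against 1563 ± 96.3 CPM (-0.53, SE 0.20, adjusted p = 0.0706) and did not pass, although it passed with DESeq2 (0.0367), limma-voom (0.0424), a surrogate variable (0.0338), the length trend removed (0.0332) and a fit of all groups (0.0119), and without Rfx3_KO replicate 1 (0.0324), 2 (0.0454) or 3 (0.0372). Rfx8 (-0.46, 0.165), Rfx4 (0.10), Rfx5 (-0.06), Rfx7 (-0.13), Rfxap (0.03) and Rfxank (0.03) did not pass. Of these, Rfx4 passed without Rfx3_KO replicate 3 (0.0130) and Rfx8 without Rfx3_KO replicate 1 (0.0217).

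Rfx1 knockouts showed few called differences. The only gene called was Scoc (ENSMUSG00000063253, chromosome 8, 83430084 to 83458391), which encodes a coiled-coil protein of the Golgi and lies near Rfx1. Scoc fell to 24.4 ± 1.19 CPM from 41.8 ± 2.57 (n = 4 and 4), a log2 difference of -0.77 (SE 0.07, adjusted p = 0.0146), with 4 of 4 knockouts below. Over ciliary genes of the Rfx1 line the median log2 difference was 0.01 over 24 axonemal dynein subunits, -0.01 over 37 genes of radial spokes, nexin links and the central pair, and -0.04 over 23 genes of dynein arm assembly and docking. These medians cover libraries that went both ways: relative to the wild types, axonemal dyneins had means of -0.20, -0.03, 0.36 and -0.46 in Rfx1_KO replicates 1 to 4, and genes of radial spokes, nexin links and the central pair -0.18, -0.01, 0.44 and -0.53. No member of a list passed over all genes, and adjusted over the list alone 2 axonemal dynein genes fell.

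Of 13830 genes tested in the Rfx1 line, 0 rose and 1 fell, while 281 had an unadjusted p under 0.05. DESeq2 called 9 genes. Leaving out Rfx1_KO replicate 2 gave 9 genes and leaving out Rfx1_WT replicate 1 gave 3, but 0 without any other library. Scoc lost its call with the replicate block (adjusted p = 0.235) and the term for Y-linked counts (0.799), and without Rfx1_KO replicates 1 (0.104), 3 (0.0784) or 4 (0.0839) or Rfx1_WT replicates 2 (0.0546), 3 (0.0575) or 4 (0.109). Of 125 genes within 10 Mb of Rfx1, 1 was called (0.8%), against 0 of 13700 elsewhere (one-sided Fisher's exact p = 0.00904, adjusted 0.0271). With 1 called gene, that p is the share of the tested genes that lie in this window. At an unadjusted p under 0.05 there were 12 of 125 (9.6%) against 1.95% elsewhere (exact p = 8.36e-06).

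Among the lists, markers of neurons and neuroblasts were higher as a set in Rfx1 knockouts, with a median log2 difference of 0.82 over 17 members (camera adjusted p = 1.49e-05; adjusted p = 0.572 with an estimated correlation; exact permutation adjusted p = 0.554). Of these members 0 passed alone, and the mean over the list in each knockout, relative to the wild types, was -0.03, 1.19, -0.15 and 0.69. In the same libraries microglia markers had means of 0.83, 1.87, 0.39 and -2.28, and oligodendrocyte lineage markers -0.26, 0.61, 0.0041 and 0.10. Gad1, an enzyme of GABA synthesis, was 4.36 ± 2.46 against 2.09 ± 0.274 CPM (n = 4 and 4), Dcx, a neuroblast microtubule protein, 14.8 ± 10.4 against 6.71 ± 1.17, and the log2 difference of Sp8 was 0.98 (each adjusted p = 0.9998). Without Rfx1_KO replicate 2 the list was no longer called (adjusted p = 0.0731). The camera test also called 3 lists lower: ciliary tubulins, tips and microtubule inner proteins (median -0.09, 33 members, adjusted p = 0.0145; adjusted p = 0.914 with an estimated correlation), IFT-B, the anterograde transport complex (-0.07, 21 members, 0.0199; adjusted p = 0.881 with an estimated correlation), and ependymal markers outside the axoneme (-0.06, 27 members, 0.0284; adjusted p = 0.857 with an estimated correlation). All 3 ended with the term for Y-linked counts (0.390, 0.213 and 0.0638), and tubulins and IFT-B turned upward without Rfx1_KO replicate 4 (0.426 and 0.862). The number of lists called moved from 4 to 2 without Rfx1_KO replicate 2, to 9 without replicate 3 or 4, and to 7 without Rfx1_WT replicate 2. Members with the smallest p in these lists were not called: Efhc2 (-0.32), Tekt3 (-0.52), Tubb4a (-0.37), Ttc30a1 (-0.27), Kif3b (-0.13), Ift22 (-0.15), Sntn (-1.06), S100b (-0.57) and Fam183b (-0.42). The same held for the planar polarity genes Vangl2 (0.29; 160 ± 16.5 against 131 ± 13.5 CPM), Fzd3 (0.12) and Celsr3 (0.80).

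Genes of the motile cilium fell broadly in Rfx2 knockouts. Of 38 genes of radial spokes, nexin links and the central pair 37 fell, as did 21 of 24 axonemal dynein subunits, the motors of ciliary beating, and 21 of 23 genes of dynein arm assembly and docking. Spef1, a protein of the central pair, fell to 26.4 ± 2.97 CPM from 63.5 ± 19.02 (n = 6 and 8; log2 difference -1.27, SE 0.18, adjusted p = 0.000221). Dnaic2, an outer-arm dynein intermediate chain, fell to 29.7 ± 3.67 from 85.1 ± 31.9 (-1.52, SE 0.23, 0.000325). Genes of transport within the cilium moved the same way, with 19 of 21 IFT-B genes lower, among them Ift46 at 69.4 ± 2.81 against 103 ± 12.9 CPM (-0.57, SE 0.07, 0.000121).

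**Figure D2:**
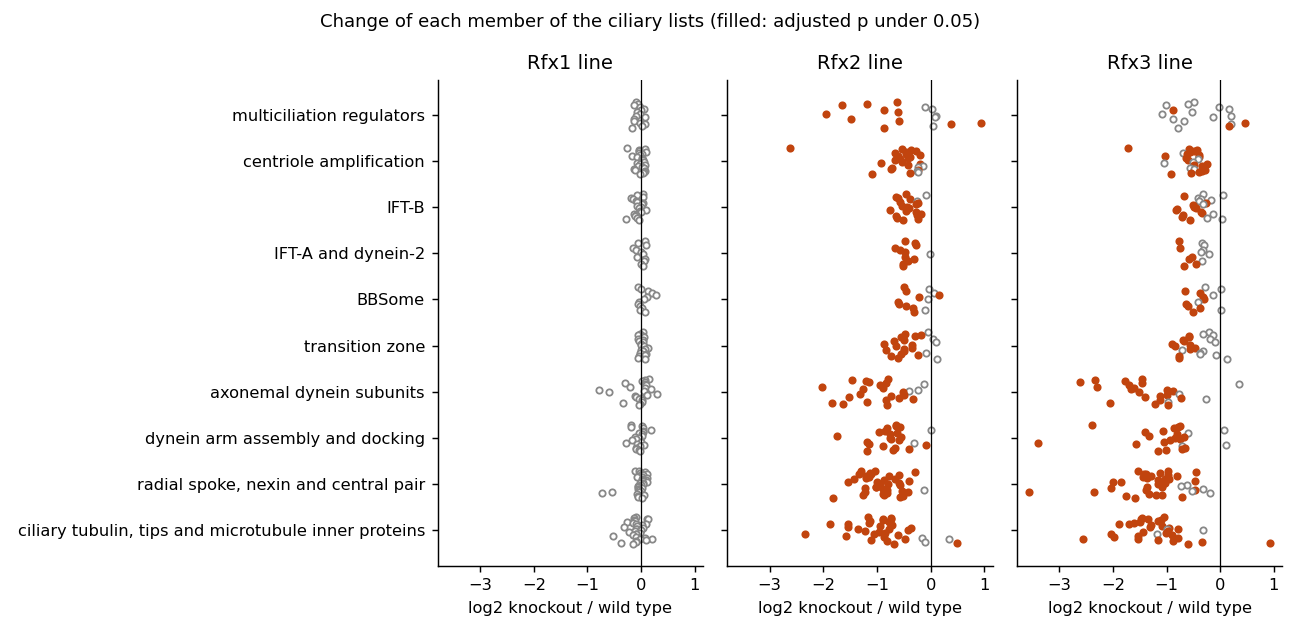
Log2 fold change of knockout over wild type for each member (point) of 10 ciliary lists in the 3 lines, filled where the gene was called. Members scatter around 0 in the Rfx1 line and lie mostly below 0 in the Rfx2 and Rfx3 lines.

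The largest decreases in Rfx2 knockouts were BC051019, 0.546 ± 0.152 CPM against 8.28 ± 4.13 (n = 6 and 8; log2 difference -3.90, SE 0.40, adjusted p = 2.95e-05), Cdhr4, a cadherin-related protein, 1.08 ± 0.173 against 14.8 ± 6.40 (-3.77, SE 0.33, 1.5e-05), and Ccdc33, 0.896 ± 0.184 against 9.65 ± 4.11 (-3.42, SE 0.33, 2.28e-05). Musk, a receptor kinase of the neuromuscular junction, was 1.37 ± 0.232 against 12.5 ± 5.49 (-3.18, SE 0.32, 2.62e-05), and Ccdc121 0.780 ± 0.233 against 5.04 ± 2.30 (-2.67, SE 0.33, 9.75e-05). The largest increases were Nwd2 (6.94 ± 1.31 against 1.41 ± 0.801; 2.29, SE 0.26, 5.84e-05), Prmt8, an arginine methyltransferase (5.11 ± 2.33 against 1.32 ± 0.414; 1.95, SE 0.27, 0.000193), and Rtp1, a chaperone of olfactory receptors (10.4 ± 1.39 against 3.13 ± 0.879; 1.73, SE 0.16, 1.84e-05). Apln, a peptide hormone of vessels, rose to 38.8 ± 4.55 from 12.4 ± 2.86 (1.64, SE 0.13, 6.01e-06) and Adamts3, a procollagen protease, to 20.3 ± 7.38 from 6.65 ± 1.99 (1.61, SE 0.23, 0.00023). In each of these 10 genes 6 of 6 knockouts lay on that side of the wild-type mean, as the rule for naming required.

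Of 14305 genes tested in the Rfx2 line 1988 rose and 2638 fell, 4626 in all, and 62 of these rose and 445 fell at least 2-fold. With the replicate number as a block 1804 rose and 2400 fell. With replicates 1 to 4 only, 2748 genes were called. The 115 genes within 10 Mb of Rfx2 were called as often as others, 37 (32.2%) against 32.3% (one-sided Fisher's exact p = 0.55). The 3 of these with the smallest p were Khsrp, an RNA-binding protein (81.4 ± 2.57 against 113 ± 5.44 CPM, n = 6 and 8; -0.47, SE 0.03, adjusted p = 5.76e-06), Catsperd (0.290 ± 0.0709 against 1.07 ± 0.264; -1.88, SE 0.21, 4.63e-05) and Guca1b (0.0107 ± 0.0166 against 0.828 ± 0.349, adjusted p = 5.23e-05).

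Camera called 12 lists lower in Rfx2 knockouts. The median log2 difference was -0.92 for radial spokes, nexin links and the central pair (38 tested; adjusted p = 7.68e-16), -0.85 for axonemal dyneins (24; 1.14e-09) and -0.70 for dynein arm assembly and docking (23; 6.97e-10). Ciliary tubulins, tips and microtubule inner proteins had 29 of 33 members lower and 1, Tubb4a, higher (median -0.86; 2.54e-11). IFT-B (19 of 21 lower, median -0.45, 1.99e-09), IFT-A and dynein-2 (11 of 12, -0.48, 7.54e-06) and the transition zone at the ciliary base (17 of 22, -0.49, 2.76e-06) followed, each with an adjusted p of 0.572 with an estimated correlation, as for the 4 lists before. Genes of centriole amplification had 22 of 26 lower (-0.44, 1.05e-08; adjusted p = 0.590 with an estimated correlation), and the BBSome, a coat for ciliary membrane cargo, 8 of 13 lower and 1 higher (-0.30, 0.00727; adjusted p = 0.675 with an estimated correlation). Regulators of multiciliation had 9 of 16 lower, among them Mcidas (18.1 ± 3.76 against 50.8 ± 19.6 CPM) and Ccno (38.2 ± 8.79 against 86.5 ± 28.5), and 2 higher (-0.60, 0.0378; adjusted p = 0.675 with an estimated correlation). Ciliary signalling genes had 12 of 22 lower and 3 higher (-0.16, 0.0370; adjusted p = 0.590 with an estimated correlation), and ependymal markers outside the axoneme 14 of 27 lower and 2 higher (-0.39, 0.000192; adjusted p = 0.572 with an estimated correlation). Ribosomal proteins were called higher, 15 of 30 (median 0.19, 1.66e-05; adjusted p = 0.572 with an estimated correlation), in a line where their median wild-type level was 28.3 CPM against 184 and 167 CPM in the Rfx1 and Rfx3 lines. Adjusted over the list alone, the members lower were 37, 22, 21, 29, 20, 11, 17, 23, 9, 10, 13 and 15 for the lists in this order.

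Further members with the smallest p in these lists included Drc1 of the nexin link (71.9 ± 5.31 against 114 ± 17.0 CPM, n = 6 and 8; -0.67, SE 0.09, adjusted p = 0.000193), Nme5 of the radial spoke (95.2 ± 6.26 against 141 ± 19.6; -0.57), Spata18 (8.55 ± 1.44 against 43.5 ± 24.0; -2.34) and 1700007K13Rik (-1.16). Among dyneins and their assembly factors Dyx1c1 was 10.3 ± 1.13 against 23.7 ± 7.59 (-1.19, SE 0.19, 0.000386), with Pih1d2 (-0.89), Dnaaf5 (-0.75), Tctex1d4 (-1.84) and Dnal4 (-0.33) also lower. Ttc30b (-0.52) and Ift20 (-0.61) fell among IFT-B genes. Markers of oligodendrocyte lineage cells were high in part of each group. Pdgfra, a marker of their precursors, was 64.4, 100 and 95.8 CPM in Rfx2_KO replicates 1 to 3 and 1.77 to 5.40 in the other knockouts, and 69.3 and 87.5 in Rfx2_WT replicates 1 and 2, 10.4 in replicate 3 and 1.96 to 3.85 in replicates 4 to 8.

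Axonemal genes fell in Rfx3 knockouts as well. Of 24 axonemal dynein subunits 20 fell, of 38 genes of radial spokes, nexin links and the central pair 33 fell, and of 33 ciliary tubulins, tips and microtubule inner proteins 29 fell. Spag16, a protein of the central pair, fell to 6.28 ± 2.67 CPM from 32.1 ± 3.12 (n = 6 and 6; log2 difference -2.35, SE 0.23, adjusted p = 0.000184), and Dnah10, an inner-arm heavy chain, to 12.2 ± 7.76 from 61.4 ± 18.01 (-2.33, SE 0.38, 0.00217). The regulators Mcidas and Foxj1 were not called, with 51.0 ± 36.8 against 93.4 ± 14.3 CPM for Mcidas. Markers of astrocytes and genes of cholesterol synthesis rose in part, 8 of 17 and 14 of 22.

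The largest decreases in Rfx3 knockouts were Fam183b, a ciliary protein (3.15 ± 6.39 against 51.1 ± 25.7 CPM, n = 6 and 6; -3.97, SE 1.02, adjusted p = 0.0155), Tmem212 (0.833 ± 0.758 against 10.2 ± 3.71; -3.65, SE 0.60, 0.00226) and Spag17 of the central pair (2.41 ± 2.28 against 28.4 ± 7.20; -3.57, SE 0.51, 0.0013). Efcab1, a calcium-binding ciliary protein (4.79 ± 3.38 against 50.8 ± 12.9; -3.40, SE 0.42, 0.000661), and Cfap73 (1.05 ± 0.757 against 11.02 ± 1.798; -3.39, SE 0.40, 0.000505) came next. Among the largest increases were Serpina3n, a protease inhibitor of reactive astrocytes (61.9 ± 60.03 against 8.28 ± 9.74; 2.90, SE 0.90, 0.0351), and Aldh1a1, an enzyme of retinoic acid synthesis (104 ± 72.6 against 23.7 ± 5.55; 2.14, SE 0.42, 0.00537). Ccn3 (6.48 ± 4.45 against 1.66 ± 0.535; 1.98, SE 0.45, 0.00939) and Grm3, a glutamate receptor (5.73 ± 4.04 against 1.46 ± 0.252; 1.98, SE 0.46, 0.0109), followed. In each of these genes 6 of 6 knockouts lay on that side of the wild-type mean, as the rule for naming required. Serpina3n was not called with limma-voom (0.104), the replicate block (0.0748), the term for Y-linked counts (0.0774) and replicates 1 to 4 only (0.143), nor without Rfx3_KO replicates 4 (0.0678), 5 (0.0693) and 6 (0.0774), or Rfx3_WT replicates 1 (0.0743), 2 (0.0707), 3 (0.0792), 4 (0.0682) and 5 (0.0732). Grm3 was not called with the term for Y-linked counts (0.0565). With replicates 1 to 4 only, Aldh1a1 (0.105), Ccn3 (0.176), Grm3 (0.200) and Fam183b (0.131) were not called.

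Of 14340 genes tested in the Rfx3 line 1517 rose and 1857 fell, 3374 in all, of which 137 rose and 570 fell at least 2-fold. The count was 5549 without Rfx3_KO replicate 3, 2139 without Rfx3_WT replicate 3, 2205 with the replicate block, 194 with replicates 1 to 4 only and 5367 in a fit of all groups. Genes within 10 Mb of Rfx3 were called as often as others, 22 of 97 (22.7%) against 23.5% (one-sided Fisher's exact p = 0.617). Those with the smallest p were 4430402I18Rik (chromosome 19, 28893042 to 28967800; 6.62 ± 1.58 against 21.6 ± 1.88 CPM, n = 6 and 6; -1.71, SE 0.14, adjusted p = 8.85e-05), Mamdc2 (95.1 ± 18.2 against 42.9 ± 5.43; 1.15, SE 0.13, 0.000333) and Il33, an alarmin cytokine (2.54 ± 0.390 against 4.96 ± 0.438; -0.97, SE 0.13, 0.000781).

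The knockout libraries of the Rfx3 line were not alike. The first principal component (51.1% of the variance) put Rfx3_KO replicates 4, 5 and 6 at 56.3, 55.6 and 63.1, replicates 1 to 3 between -2.50 and 2.66, and the wild types between -39.8 and -16.3, while Rfx3_KO replicate 3 alone lay at -67.9 on the second (22.3%). Regulators of multiciliation followed this division: relative to the wild types, their mean log2 level was 0.03, 0.03 and -0.14 in Rfx3_KO replicates 1 to 3 and -0.97, -0.87 and -1.21 in replicates 4 to 6. Axonemal dyneins were lower in all 6, by -0.69, -0.72, -1.55, -1.83, -1.797 and -2.32 in that order. The deviation of Rfx3_KO replicate 3 from the other knockouts went with transcript length (Spearman rho -0.68 over genes). For the other knockouts that rho was 0.05 to 0.44. The mean of replicate 3 over dynein arm assembly and docking was -0.73, so its value for axonemal dyneins may not reflect genotype alone. Mcidas was 93.7, 90.4, 65.7, 19.998, 22.5 and 13.3 CPM, against 68.9 to 112 in wild types, and Foxj1 1481, 1435, 1373, 762, 765 and 680, against 1440.1 to 1732. Gfap, an astrocyte filament, was 2211, 2414 and 2190 CPM in replicates 4 to 6 and 637 to 1157 in replicates 1 to 3. Rfx3_WT replicate 6 also stood apart, with 2106 CPM of Gfap against 286 to 798 in the other wild types, and a mean of 2.20 for oligodendrocyte and 1.89 for microglia markers. Oligodendrocyte markers had means of 1.43, -0.23, -0.29, 1.99, 2.65 and 1.23 in Rfx3_KO replicates 1 to 6.

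**Figure D3:**
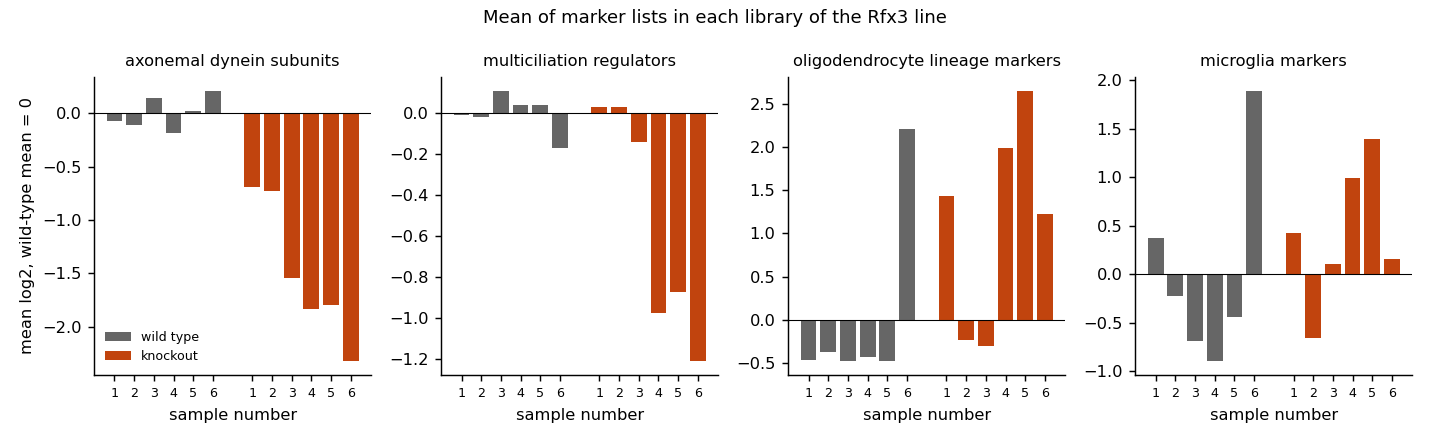
Mean log2 level of 4 marker lists in each library of the Rfx3 line, relative to the mean of the wild types. Axonemal dyneins are below 0 in 6 of 6 knockouts, regulators of multiciliation lie at 0.03, 0.03 and -0.14 in replicates 1 to 3, and oligodendrocyte markers are high in Rfx3_WT replicate 6 and in Rfx3_KO replicates 1, 4, 5 and 6.

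Camera called 12 lists lower in Rfx3 knockouts. The lists of radial spokes, nexin links and the central pair (median -1.14, 33 of 38 lower, adjusted p = 1.48e-16), tubulins, tips and inner proteins (-1.17, 29 of 33, 2.09e-13), axonemal dyneins (-1.32, 20 of 24, 2.64e-12) and dynein arm assembly and docking (-0.84, 19 of 23, 9.3e-10) came first. Centriole amplification (-0.51, 20 of 26, 2.65e-10), IFT-B (-0.37, 12 of 22, 4.28e-07), IFT-A and dynein-2 (-0.41, 6 of 12, 4.53e-05), the transition zone (-0.52, 11 of 22, 2.76e-06), ependymal markers outside the axoneme (-0.70, 15 of 27 lower and 1 higher, 1.66e-05) and choroid plexus markers (-0.54, 7 of 13, 0.0374) were also lower. Each of these 10 had an adjusted p of 0.572 with an estimated correlation. The BBSome (-0.38, 8 of 13, 0.000211; adjusted p = 0.591 with an estimated correlation) and ciliary signalling (-0.19, 7 of 22 lower and 1 higher, 0.0234; adjusted p = 0.635 with an estimated correlation) completed the set. Adjusted over the list alone, 36, 31, 23, 21, 23, 14, 7, 12, 18, 7, 9 and 8 members were lower in this order. Regulators of multiciliation were not called (-0.51, 1 of 16 lower and 2 higher, adjusted p = 0.253).

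Among members with the smallest p, Efhb (17.3 ± 6.01 against 42.1 ± 2.84 CPM, n = 6 and 6; -1.28, SE 0.18, adjusted p = 0.00128), Ttll10 (-2.56, 0.00275), Dnah14 (-1.46, 0.00203), Armc4, a docking factor (3.77 ± 2.29 against 19.7 ± 4.17; -2.39, SE 0.34, 0.00121), Ccdc78 (4.25 ± 2.03 against 13.99 ± 1.86; -1.72, SE 0.27, 0.00194) and Iqub (67.6 ± 21.9 against 138 ± 6.05; -1.03, SE 0.17, 0.00267) fell. Ttc25 (39.6 ± 13.4 against 79.7 ± 7.24; -1.01, 0.00443), Cep83 (54.6 ± 19.1 against 111 ± 5.81; -1.02, 0.00444) and Cep164 (72.4 ± 15.1 against 111 ± 9.24; -0.62, 0.00576), the last a distal appendage protein, fell as well. Dnah7c (-1.51, 0.00158) has near-identical copies, so its reads cannot be placed with certainty. Tubb4a, a beta-tubulin, rose to 51.8 ± 3.56 from 27.2 ± 3.84 (0.93, SE 0.09, 0.000184). With replicates 1 to 4 only, Iqub (0.0663), Dnah7c (0.0598), Dnah14 (0.0717), Cep83 (0.0707), Cep164 (0.143) and Ttc25 (0.0784) were not called.

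Camera called 7 lists higher in Rfx3 knockouts. Cholesterol synthesis had 14 of 22 members higher (median 0.40, adjusted p = 1.66e-05; adjusted p = 0.591 with an estimated correlation) and ribosomal proteins 12 of 30 (0.38, 2.83e-07; adjusted p = 0.729 with an estimated correlation), with a mean of 0.99 in Rfx3_KO replicate 3 and 0.17 to 0.24 in the other knockouts. Cell cycle genes had 10 of 27 higher (0.23, 0.00114; adjusted p = 0.779 with an estimated correlation) and astrocyte markers 8 of 17 (0.32, 0.00417; adjusted p = 0.590 with an estimated correlation). Immediate early genes had 3 of 16 (0.28, 0.0227; adjusted p = 0.731 with an estimated correlation), oligodendrocyte lineage markers 2 of 14 (0.96, 0.0234; adjusted p = 0.794 with an estimated correlation), and the unfolded protein response 4 of 15 with 1 lower (0.23, 0.0450; adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 15, 22, 11, 8, 3, 2 and 7 members were higher. Several rises were largest in Rfx3_KO replicates 4 to 6. Relative to the wild types, cell cycle means were -0.02 to 0.22 in replicates 1 to 3 and 0.28 to 0.54 in replicates 4 to 6. Those of cholesterol synthesis were 0.04 to 0.26 and 0.46 to 0.62, and of immediate early genes -0.09 to 0.20 and 0.48 to 0.60. Astrocyte markers had 0.12 to 0.27 and 0.37 to 0.60, while the unfolded protein response was highest in replicate 3 (0.41). By the exact permutation test of library means, cholesterol synthesis (adjusted p = 0.0145) and ribosomal proteins (0.0084) passed and the other 5 did not (0.0556 to 0.254).

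More genes were called in the same direction in the Rfx2 and Rfx3 lines than independent lists of independent genes would share. Plekha2 (ENSMUSG00000031557), a phosphoinositide-binding adaptor, fell in Rfx2 knockouts (101 ± 4.69 against 161 ± 18.4 CPM, n = 6 and 8; -0.67, SE 0.07, adjusted p = 3.72e-05) and in Rfx3 knockouts (86.5 ± 9.08 against 167 ± 17.5, n = 6 and 6; -0.94, SE 0.09, 0.000107), and differed by 0.15 in Rfx1 knockouts. Kcnmb1 (ENSMUSG00000020155), a potassium channel subunit, fell in both (-2.06, SE 0.24, 6.32e-05 and -2.12, SE 0.21, 0.000158), as did the receptor Gprc5c (ENSMUSG00000051043; -2.27, SE 0.22, 2.09e-05 and -1.65, SE 0.19, 0.000437). Apln (ENSMUSG00000037010) rose in both, in Rfx3 knockouts to 44.9 ± 8.47 from 17.9 ± 3.03 CPM (1.32, SE 0.15, 0.000374), and so did Asphd2 (ENSMUSG00000029348; 0.71, SE 0.08, 6.32e-05 and 0.74, SE 0.07, 0.000213).

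Of 14086 genes tested in both lines, 1216 fell in both (of 2627 and 1821; 340 expected under independence; odds ratio 15.5, one-sided lower 95% bound 14.05) and 458 rose in both (of 1974 and 1506; 211 expected; odds ratio 3.19, lower bound 2.87, one-sided Fisher's exact p = 4.51e-69). That is 1674 genes changed the same way, against 56 called in opposite directions. Fisher's test takes genes as independent, and genes that move together are not, so its p and bounds can overstate the evidence. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.66 and a Spearman rho of 0.58. The count was 1279 with the replicate block, 91 with replicates 1 to 4 only and 2635 without Rfx3_KO replicate 3. Rfx1 shared 0 calls with either line, having 1 call in all, and its correlation across genes was r = 0.30, rho = 0.29 with Rfx2 and r = 0.14, rho = 0.06 with Rfx3. DESeq2 gave 1 shared gene with Rfx2 and 2 with Rfx3.

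**Figure D4:**
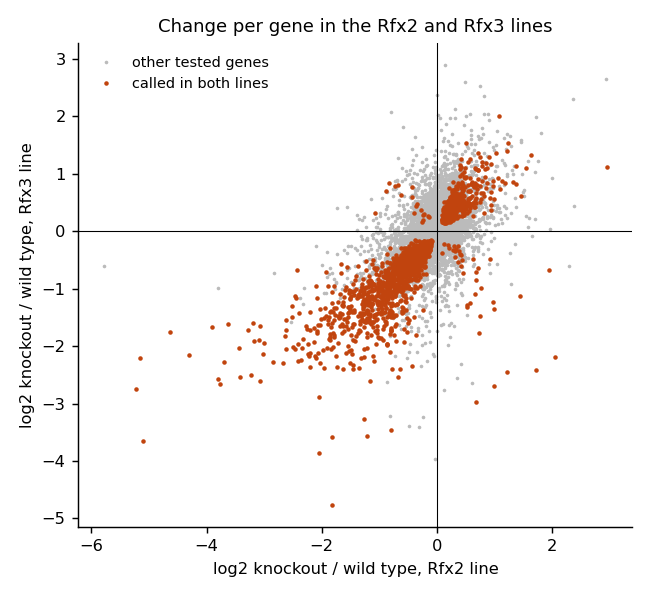
Log2 fold change of each gene in the Rfx2 line (x axis) against the Rfx3 line (y axis), with genes called in both lines in colour. Of these, 1674 changed the same way and 56 in opposite directions.

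The knockout effects were also compared directly between lines. Avpr1a, a vasopressin receptor, rose in Rfx2 knockouts (19.3 ± 9.06 against 9.69 ± 3.07 CPM, n = 6 and 8; 0.99) and fell in Rfx3 knockouts (1.76 ± 0.424 against 11.3 ± 3.27, n = 6 and 6; -2.69), a difference of 3.70 (SE 0.40, adjusted p = 2.34e-07). Sphkap, a kinase-anchoring protein, likewise rose to 8.38 ± 1.56 from 3.59 ± 0.857 in Rfx2 knockouts (1.23) and fell to 0.543 ± 0.177 from 3.02 ± 0.340 in Rfx3 knockouts (-2.46), a difference of 3.69 (SE 0.29, 3.05e-10). Fam183b differed by 3.95 (SE 0.88, 0.00744) with -0.02 in Rfx2 knockouts. Stronger in Rfx2 knockouts was the decrease of BC051019 (-2.22, SE 0.62, 0.0381), and stronger in Rfx3 knockouts were the increases of Grm3 (-1.74, SE 0.50, 0.0414) and Sema7a, a semaphorin (10.4 ± 6.30 against 3.08 ± 0.703 CPM; -1.67, SE 0.45, 0.0319). In all, 570 of 14833 genes differed between these lines, 312 with the higher change in Rfx2 and 258 in Rfx3. With the replicate block there were 342, with DESeq2 911, with replicates 1 to 4 only 81, and without Rfx3_KO replicate 2 there were 961. Fam183b was not called with replicates 1 to 4 only (0.153). BC051019 was not called with limma-voom (0.316), the replicate block (0.150) and a surrogate variable (0.0522), nor without Rfx2_KO replicates 4 (0.0533), 5 (0.0522) and 6 (0.0614), or Rfx2_WT replicate 2 (0.0532), or Rfx3_KO replicates 1 (0.0650) and 3 (0.0557), or Rfx3_WT replicates 1 (0.0575), 2 (0.0536), 4 (0.0568), 5 (0.0506) and 6 (0.0518). Grm3 was not called with limma-voom (0.175), no low-count filter (0.0507), the replicate block (0.178), the term for Y-linked counts (0.0687), thinning (0.0627), replicates 1 to 4 only (0.531) and the compared groups alone (0.0538), nor without Rfx2_KO replicates 4 (0.0648), 5 (0.0501) and 6 (0.0542), or Rfx2_WT replicates 1 (0.0605), 2 (0.0614), 6 (0.0527) and 8 (0.0521), or Rfx3_KO replicates 4 (0.0726), 5 (0.0742) and 6 (0.0818), or Rfx3_WT replicates 1 (0.0619), 2 (0.0516), 3 (0.0761), 4 (0.0572) and 5 (0.0743). Sema7a was not called with limma-voom (0.0773), the replicate block (0.0964), the term for Y-linked counts (0.0527) and replicates 1 to 4 only (0.470), nor without Rfx3_KO replicates 4 (0.0641) and 6 (0.0608), or Rfx3_WT replicates 1 (0.0572), 4 (0.0516) and 5 (0.0603).

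Between the Rfx1 and Rfx2 lines 123 genes differed, 88 with the higher change in Rfx1. Ccdc33 (difference 3.32, SE 0.60, adjusted p = 0.00381), BC051019 (3.21, SE 0.69, 0.0171) and Musk (3.02, SE 0.57, 0.00552) were among those lower in Rfx2 knockouts. Rtp1 (-2.21, SE 0.41, 0.00487), Adamts3 (-1.55, SE 0.39, 0.0458) and Cpxm2, a carboxypeptidase-like protein (-1.51, SE 0.33, 0.0205; 54.3 ± 6.64 against 21.7 ± 7.87 CPM in the Rfx2 line, n = 6 and 8), were higher there. With the replicate block 51 genes were called, 46 of them among the 123, and DESeq2 gave 331, limma-voom 57, the length trend removed 222 and the compared groups alone 423. BC051019 was not called with limma-voom (0.123) and the replicate block (0.0597), nor without Rfx1_KO replicate 3 (0.0780). Musk was not called with the replicate block (0.0760). Adamts3 was not called with scaling by library size alone (0.0504), limma-voom (0.198), no low-count filter (0.0567), the replicate block (0.174), the term for Y-linked counts (0.0645), thinning (0.0589) and replicates 1 to 4 only (0.124), nor without Rfx1_KO replicates 1 (0.0652), 2 (0.0718) and 3 (0.156), or Rfx1_WT replicates 1 (0.0678), 2 (0.171) and 3 (0.103), or Rfx2_KO replicates 4 (0.0843), 5 (0.0663) and 6 (0.0895), or Rfx2_WT replicates 2 (0.0682), 3 (0.0598), 4 (0.0577), 6 (0.0781), 7 (0.0671) and 8 (0.0748), or Rfx3_KO replicate 4 (0.0546), or Rfx3_WT replicates 1 (0.0534), 2 (0.0548), 3 (0.0548) and 5 (0.0540). Cpxm2 was not called with limma-voom (0.0768), the replicate block (0.0597) and replicates 1 to 4 only (0.0628), nor without Rfx1_WT replicate 1 (0.0649). The effect on Rfx1 mRNA itself also differed (-1.31, SE 0.16, adjusted p = 6.06e-05). Between the Rfx1 and Rfx3 lines 1149 genes differed, 711 with the higher change in Rfx1. The count was 415 with the compared groups alone and 52 with replicates 1 to 4 only. Fam183b (3.53, SE 1.04, 0.0336), Cfap73 (3.30, SE 0.50, 0.000222) and Avpr1a (3.21, SE 0.46, 0.000123) were lower in Rfx3 knockouts, and Aldh1a1 (-2.39, SE 0.66, 0.0259) and Scrg1 (-2.06, SE 0.60, 0.0328; 12.9 ± 6.52 against 3.30 ± 2.18 CPM in the Rfx3 line, n = 6 and 6) higher. Fam183b was not called with replicates 1 to 4 only (0.194) and the compared groups alone (0.113), nor without Rfx1_KO replicate 3 (0.123), or Rfx1_WT replicates 1 (0.0620), 2 (0.0819) and 3 (0.0621), or Rfx3_KO replicate 6 (0.0507), or Rfx3_WT replicates 1 (0.0503) and 3 (0.0560). Aldh1a1 was not called with limma-voom (0.0881), the replicate block (0.0503) and replicates 1 to 4 only (0.176), nor without Rfx1_KO replicate 3 (0.0850), or Rfx1_WT replicate 2 (0.0717), or Rfx3_KO replicate 6 (0.0546). Scrg1 was not called with limma-voom (0.0548), the term for Y-linked counts (0.0695), replicates 1 to 4 only (0.139) and the compared groups alone (0.0984), nor without Rfx1_KO replicates 2 (0.0559), 3 (0.0984) and 4 (0.0521), or Rfx1_WT replicate 1 (0.109), or Rfx3_KO replicates 4 (0.0526), 5 (0.0583) and 6 (0.0503), or Rfx3_WT replicates 3 (0.0578) and 5 (0.0518).

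These counts moved with single libraries. For Rfx1 against Rfx2 it was 46, 73, 63 and 62 without Rfx1_KO replicate 3 and Rfx1_WT replicates 1, 2 and 3, and 81, 73, 77 and 75 without Rfx2_WT replicates 2, 3, 4 and 8. It was 200, 254, 264, 292 and 194 without Rfx1_KO replicate 4, Rfx2_WT replicates 1 and 5, and Rfx3_KO replicates 3 and 6. For Rfx1 against Rfx3 it was 286, 657 and 493 without Rfx1_KO replicate 3 and Rfx1_WT replicates 1 and 2, 711 and 722 without Rfx3_KO replicate 6 and Rfx3_WT replicate 3, and 2041, 1986 and 1726 without Rfx3_KO replicates 1, 2 and 3.

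The wild-type groups of the 3 lines differed from each other in 8566 of 14833 genes. Gapdh was 3.49 to 6.32 CPM in all 14 libraries of the Rfx2 line, knockouts included, against 347 to 416 in the Rfx1 line and 315 to 456 in the Rfx3 line. In Rfx2 wild types Actg1, a cytoplasmic actin, was 62.9-fold lower than the mean of the other lines, Rps6 254-fold and Rps29 580-fold (adjusted p = 4.83e-32, 5.59e-29 and 4.29e-27). Genes at least 2-fold lower in the Rfx2 wild types made up 1.46%, 2.89%, 12.03%, 25% and 34.3% of genes with 0 to 5, 5 to 20, 20 to 50, 50 to 80 and 80 to 100% of their 31-mers in transcripts of other genes.

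**Figure D5:**
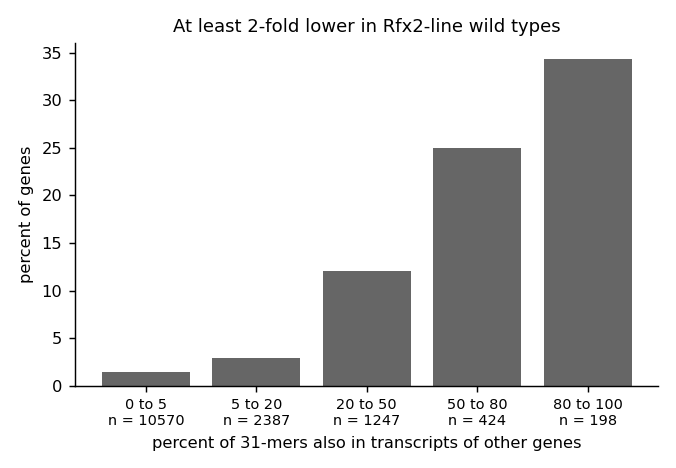
Percent of genes at least 2-fold lower in the wild types of the Rfx2 line than in those of the other lines (y axis), by the percent of a gene's 31-mers also found in transcripts of other genes (x axis; n, genes in each bin). The share rises from 1.46% to 34.3%.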

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

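The relation of Rfx3_KO replicate 3 with transcript length was tested only after that relation had been seen, and the permutations within replicate pairs were added after the results were seen.

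In 278 checks of a sample against the others of its group, 19 (6.83%) lay far from the rest. The limit used is passed by chance in about 1 in 20 checks of independent, normally distributed values. CPM of genes that move together need not be such values, so 6.83% cannot be judged against that rate. Rfx3_WT replicate 6 accounts for 6 of the 19, among them Serpina3n at 27.9 CPM (nearest other 6.61), Tmem212 at 17.4 (10.2), Efcab1 at 75.8 (50.2), Ttll10 at 5.43 (2.71) and Scrg1 at 7.58 (3.41). Rfx3_KO replicate 3 accounts for 3, with Rfx5 at 27.6 CPM (44.3), Rfx7 at 35.9 (63.2) and Rfxap at 63.5 (44.0). In Rfx3_KO replicate 1 Fam183b was 16.2 CPM (1.35), and in Rfx3_WT replicate 4 Rfxank was 10.7 (11.9) and Spag16 26.1 (32.3). In the Rfx2 line Rfx7 was 81.8 CPM (73.2) and Gprc5c 4.08 (2.86) in Rfx2_KO replicate 5, and Nwd2 3.36 (1.37) and Apln 19.1 (12.4) in Rfx2_WT replicate 5. In the Rfx1 line Ccdc33 was 8.10 CPM (13.1) in Rfx1_WT replicate 2, and Rfx1_WT replicate 4 had 50.9 M counts (21.5).

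Rfx3_KO replicate 3 stood apart from the other knockouts of its line: the SD over genes of its log2 deviation from their mean was 0.696, against 0.396 to 0.450 for the others. A trend with GC content and depth are argued against as whole causes, since the SD was 0.687 with the GC trend removed and 0.689 after thinning to the smallest total. With the length trend removed it was 0.548 (highest other 0.442), so a length trend may account for part of it, and this test left open whether it is the main cause. A difference between embryos or cultures stays open and was not tested.

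The knockout effect differed between lines in 123 genes (Rfx1 against Rfx2), 1149 (Rfx1 against Rfx3) and 570 (Rfx2 against Rfx3), by tests of the difference itself. Rfx1 minus Rfx2 was 3.32 for Ccdc33, 3.21 for BC051019, 3.02 for Musk, -2.21 for Rtp1, -1.55 for Adamts3 and -1.51 for Cpxm2. Rfx1 minus Rfx3 was 3.53 for Fam183b, 3.30 for Cfap73, 3.21 for Avpr1a, -2.39 for Aldh1a1 and -2.06 for Scrg1. Rfx2 minus Rfx3 was 3.95 for Fam183b, 3.70 for Avpr1a, 3.69 for Sphkap, -2.22 for BC051019, -1.74 for Grm3 and -1.67 for Sema7a. With genotypes permuted within lines, 1 of 100, 1 of 100 and 3 of 100 arrangements, the real one included, gave as many genes. Each share met the bound set beforehand. These permutations took away the knockout effects of every line, so they did not test whether the effects of the lines were equal. Only in that sense was chance excluded for Rfx1 against Rfx3. The highest of the others were 2, 3 and 2650. The last, several times the real 570, points to a structure of the samples besides genotype. For Rfx2 against Rfx3 chance is therefore not firmly excluded, although the bound was met. With Rfx2 genotypes exchanged only within pairs of replicate numbers, the shares were again 1, 1 and 3 of 100. The highest others were 111, 66 and 3513, the first close to the real 123. Chance is therefore not firmly excluded for Rfx1 against Rfx2 either. With the replicate block the counts were 51 for Rfx1 against Rfx2 and 342 for Rfx2 against Rfx3.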

How the results depend on the processing

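The term for Y-linked counts, the removal of the length trend and the exact permutation of library means were chosen only after the results were seen.

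For genes named in the text, 3199 combinations of gene and setting kept direction and side of the threshold, 159 lost and 16 gained a call, and 26 turned direction, with no call on either side. The causes of these changes were not tested, though a stricter threshold lowers a count by definition. Fewer samples need not lower it, as the Rfx3 count rose from 3374 to 5549 without Rfx3_KO replicate 3. An adjusted p below 0.01 gave 0, 2740 and 1217 genes for the Rfx1, Rfx2 and Rfx3 lines, 36, 208 and 220 for the differences Rfx1 against Rfx2, Rfx1 against Rfx3 and Rfx2 against Rfx3, and 535 shared by Rfx2 and Rfx3. A log2 change of at least 1 gave 0, 507 and 707, then 71, 416 and 190, then 288. Replicates 1 to 4 only gave 2748 (Rfx2), 194 (Rfx3), 52 and 81 (Rfx1 and Rfx2 against Rfx3) and 91 shared. The replicate block gave 0 (Rfx1), 2205 (Rfx3), 51 (Rfx1 against Rfx2), 342 (Rfx2 against Rfx3) and 0 genes near Rfx1. In the Rfx2 line it changed the call of Rfx8 and of the interferon and microglia lists, and of no other named gene or list. DESeq2 gave 9 (Rfx1), 331 and 911 (Rfx2 against Rfx1 and Rfx3), 1 and 2 shared by Rfx1 with Rfx2 and Rfx3, and 4 near Rfx1. A fit of all groups gave 6 (Rfx1), 5367 (Rfx3) and 1 and 1 shared by Rfx1. For Rfx1, edgeR gave 2 genes with no low-count filter and 0 with the term for Y-linked counts, against 281 at an unadjusted p under 0.05. For Rfx1 against Rfx2, limma-voom gave 57, the length trend removed 222 and the compared groups alone 423; the last gave 415 for Rfx1 against Rfx3. A 5 Mb window gave 19 genes near Rfx2. An estimated correlation gave 0 lists in each line, fry 1 and exact permutation 0 in the Rfx1 line. Leaving out 1 library gave 0 to 9, 3974 to 5270 and 2139 to 5549 genes for the lines, 46 to 292, 286 to 2041 and 412 to 961 for differences, 7970 to 9981 between wild types, 0 to 0, 0 to 1 and 1146 to 2635 shared, and 2 to 9, 11 to 14 and 16 to 22 lists.

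Direction turned for genes not called in either fit. With the term for Y-linked counts in the Rfx1 line, Rfx4 was -0.0020, Rfx7 -0.076, Rfxap 0.037, Rfxank 0.018 and Tubb4a 0.085 (reported as -0.37). In that line Rfx8 was 0.0043 with limma-voom and Rfxank 0.022 after thinning. With 1 library left out, Rfx7 ran from -0.0071 to 0.063, Rfx8 from -0.18 to 0.12, Rfxank from -0.080 to 0.061 and Foxj1 from -0.20 to 0.019. In the Rfx2 line Rfx4 was 0.0067 with a surrogate variable and 0.054 with replicates 1 to 4, Rfx7 0.00053 in a fit of all groups, and Rfxap -0.012 to 0.057 with 1 library left out. In the Rfx3 line Rfxap was -0.0055 with limma-voom and -0.045 with the length trend removed. With 1 library left out Rfxap ran from -0.12 to 0.10, Rfx5 from -0.096 to 0.036 and Rfxank from -0.011 to 0.083, each turning without Rfx3_KO replicate 3. On simulated data with the sample numbers of the Rfx1 line, 28 of 50 genes changed 1.5-fold and 43 of 50 changed 2-fold were called. The simulated samples held no structure besides genotype, so these shares do not bound the effects that the real fit can miss. In the real fit Rfx1 mRNA itself was not called by edgeR (log2 difference -1.40, adjusted p = 0.0687), with 4 of 4 knockouts below the wild-type mean. Effects of Rfx1 larger than 2-fold can therefore also be missed.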

Other observations

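The test on the share of genes at least 2-fold lower, the tests on dynein heavy chains, the splits of the Rfx2 line by replicate pairs, the exact test of lists and the list tests with the length trend removed were chosen only after the results were seen.

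Planar polarity genes, which orient cilia in the plane of the tissue, went both ways in Rfx2 knockouts, with 6 of 16 higher and 3 lower (median 0.08, camera adjusted p = 0.373), though the list passed as higher with fry (0.0233) and the exact test (0.0363; 6 of 6 knockouts on that side). Vangl2, a core member, rose by 0.85 in log2 (adjusted p = 6.01e-06). Neuron and neuroblast markers had 2 of 15 members higher (median 0.45, adjusted p = 0.106), though they passed with fry (0.000399) and the exact test (0.0237). Of interferon genes 6 of 21 were lower (median -0.22, adjusted p = 0.0501; 0.0127 with the replicate block). Other lists not called by camera in the Rfx2 line, with members higher and lower, were the RFX family (0 and 2, exact test 0.00840), hedgehog targets (3 and 1), Notch pathway (4 and 3), astrocyte (4 and 2), oligodendrocyte (1 and 1), microglia (0 and 0, adjusted p = 0.134, but 0.0179 with the replicate block), endothelial (2 and 1), fibroblast (3 and 1) and choroid plexus markers (2 and 3). The same held for cell cycle (0 and 1), cholesterol synthesis (3 and 2), immediate early (0 and 1), extracellular matrix (1 and 2), unfolded protein response (1 and 1), hypoxia and glycolysis (2 and 4, exact test 0.00870), lipid (0 and 0) and MHC class II genes (0 and 0). The RFX family list includes the targeted gene Rfx2 itself (-1.13), so its fall is partly set by the knockout.

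In Rfx3 knockouts the lists not called by camera were the RFX family (0 higher and 3 lower, adjusted p = 0.0518; fry 0.00594, exact test 0.00840), Notch pathway (3 and 0, 0.0690, fry 0.0194), hedgehog targets (3 and 1), planar polarity (1 and 3), neuron (4 and 3), microglia (0 and 0), endothelial (2 and 0, fry 0.0207) and fibroblast markers (2 and 0), interferon (1 and 1), extracellular matrix (6 and 2), hypoxia and glycolysis (4 and 3) and lipid genes (3 and 0). Here too the RFX family list includes the targeted gene, Rfx3 (-2.14), so its fall is partly set by the knockout. In Rfx1 knockouts the other lists had camera adjusted p of 0.0501 (planar polarity), 0.0818 (immediate early genes) and 0.149 or more, and by fry hypoxia and glycolysis passed (0.0257). Rtp1 rose in Rfx2 knockouts (1.73) and fell in Rfx3 knockouts (-2.42, adjusted p = 0.00149), a difference of 4.15 (adjusted p = 3.15e-08). Over the libraries of these lines its mean was below the level set for naming a difference, so it was not named there. Ttr, a choroid plexus transcript, was 26.7 CPM in Rfx1_KO replicate 2, 3.75 in Rfx1_WT replicate 4 and at most 0.441 in the other Rfx1 libraries.

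Axonemal genes were lower in Rfx2 and Rfx3 knockouts. A smaller share of multiciliated cells with unaltered expression per cell would lower alike all genes expressed in no other cells. In the Rfx3 line 89 members spread with an SD of 0.68 (highest other 0.575, exact p = 0.00216 over 924 splits, the smallest they can give). The 13 dynein heavy chains spread with 0.67 (highest other 0.574). That argues against such a share as the whole cause only for genes expressed in multiciliated cells alone. Members also expressed in other cells would fall less under it, and their expression there was not measured. An added smaller share stays open. In the Rfx2 line the SD was 0.44 over members (exact p = 0.000666 over 3003 splits; highest other 0.445) and 0.47 over 12 heavy chains (0.000333; highest other 0.471), and over the 64 splits that part every pair it was the highest (exact p = 0.0156, the smallest they can give; highest others 0.365 and 0.405). That goes against an equal fall of these genes. But the SD over members fell short of the bound set beforehand, and that over heavy chains of the same bound, set there afterwards. The explanation therefore stays open. The heavy chain that fell least in the Rfx2 line was Dnah7a (-0.22, against -1.87 for Dnah3). As for Dnah7c, its reads may not be placed with certainty, and the spread without it was not tested. A length trend as the whole cause is argued against. With it removed, 11 of 12 and 10 of 11 ciliary lists lower in the Rfx2 and Rfx3 lines stayed called. Those calls used the preset correlation, and other splits of these lines often gave as many called lists, so this evidence is weak.

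Gapdh was 3.49 to 6.32 CPM in the Rfx2 line, with a wild-type log2 difference of -6.53 from the Rfx1 and -6.22 from the Rfx3 line. A lower glycolytic program is argued against as the whole cause by 14 other genes of hypoxia and glycolysis, whose median difference was 0.0235 and whose lowest was -3.10 (highest 0.62). Reads shared with near-identical copies, handled differently in the Rfx2 libraries, may be the cause: 28.0% of 622 genes with at least 50% shared 31-mers were at least 2-fold lower, against 1.46% of 10570 with under 5%. The test set beforehand left this undecided, since the difference between the medians was -0.26 (bootstrap interval -0.352 to -0.219), short of the -1 it asked for. Only 31.9% of the 31-mers of Gapdh itself were shared with annotated transcripts, and unannotated pseudogenes were not searched. No label gives a batch, so a difference in library handling stays open.

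For the number of genes called, 1 of 100 splits, the real one included, was as large in the Rfx2 line (4626, highest other 2254). The same held in the Rfx3 line (3374, highest other 785). That excludes chance only if the samples of a line are exchangeable. The Rfx2 numbers behaved like pairs, and Rfx3_KO replicates 4 to 6 stood apart from replicates 1 to 3. A grouping by embryo or culture that goes with genotype was therefore not excluded. In the Rfx1 line 4 of 35 splits gave as many as the real 1, and the highest, 276, set Rfx1_KO replicates 1 and 3 with Rfx1_WT replicates 1 and 4 against the rest, so chance was not excluded and the samples hold another structure. Of the 64 Rfx2 splits that part every pair of replicate numbers, the highest other gave 2485, with replicate 5 swapped, and their median was 0. The genes shared by Rfx2 and Rfx3 (1674, highest other 0, 1 of 100) follow the numbers called in each line, so their splits say nothing further of the sharing. Rfx1 shared 0 genes with Rfx2 and with Rfx3 by edgeR (DESeq2 1 and 2; 281 Rfx1 genes at an unadjusted p under 0.05), which fixes the outcome at 35 of 35 splits and tests nothing. On the same condition of exchangeable samples, chance was excluded for the wild-type groups (8566, highest other 3514, 1 of 100). The counts near Rfx2 (37, highest other 15) and Rfx3 (22, highest other 7) follow the number of genes called in all, so their splits say nothing of the locus. Near Rfx1 (1, highest other 1, 2 of 35) chance was not excluded. For the number of lists called it was not excluded: 34 of 35 splits in the Rfx1 line (4, highest other 19), 38 of 100 in the Rfx2 line (13, highest other 20) and 26 of 100 in the Rfx3 line (19, highest other 23) gave as many.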
